A study of Caenorhabditis elegans with 6 samples.

How the data were processed

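RNA was measured in 6 libraries of whole C. elegans N2 hermaphrodites kept at 20 °C, 3 fed control RNAi bacteria and 3 fed fars-1 RNAi bacteria according to the labels. Total RNA was extracted with RNAiso plus and sequenced as paired ends on an Illumina instrument. The strand setting, the library selection and the annotation release are not given in the sources used here. Per the file headers the deposited values are expected counts (expected_counts) per gene, 1 library per file, which the authors did not scale between libraries. The authors' processing notes name STAR 2.7.0e, RSEM 1.3.1 and the genome build WBcel235 (ce11). The files hold no TPM (length-scaled transcript shares) and no effective lengths, so the planned TPM of fars-1 is not given.

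Each file lists 46904 genes, of which 46817 (99.8%) matched the Ensembl 115 annotation of WBcel235, used for symbols and coordinates. The 12 mitochondrial mRNAs were named by position. Totals ran from 25889448 to 34307717 counts per library. Expected counts were rounded, filtered with filterByExpr by group and scaled by TMM factors in edgeR 4.0.16 (R 4.3.3). The edgeR quasi-likelihood test compared the groups with group as the only term, and p-values were adjusted by Benjamini-Hochberg over the 15959 genes tested, with a threshold of 0.05. CPM use TMM-scaled library sizes. Where a group held few counts, exact 95% intervals of the ratio of pooled counts are given, and a group at 0 was set to a floor of 3 counts over the group.

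Gene lists (49, with 1220 names, of which 45 did not match), the tests and, except where stated below, the alternatives were fixed before the data were examined. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and the preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry, which tests the direction of a list on its own, were run beside it. The 24 lists that passed camera with the preset correlation all missed the threshold with an estimated one. The estimated version takes its degrees of freedom from the 6 libraries, whereas the preset version takes them from the genes. With so few libraries the estimated version had little power, so a miss there is weak evidence against a list. Genes named were fars-1, then among genes past the threshold with a mean of at least 5 CPM and separate groups the 12 with the largest rises and the 12 with the largest falls, and up to 3 members per list with the smallest p. Other genes named, of the 201 with values, were chosen after their values were seen, as was the test of families by name prefix. Shares of counts were compared by exact two-sided permutation tests, whose smallest p is 0.1 for 3 against 3 libraries.

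The alternatives were RLE, upper-quartile and total-count scaling, no low-count filter, CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) with TPM from rounded counts and annotated exon length, a replicate block, a test against a 2-fold change, a prior count of 0.5, and leaving out each library. A fit without mitochondrial genes, and list tests with upper-quartile and total-count scaling, were chosen after seeing the data. Effective lengths as offsets could not be used because the files lack them. The procedure was tested on simulated data with 50 genes changed at each fold, where it found 30% of 1.5-fold, 74% of 2-fold and 100% of 4-fold changes, and 9.52% of calls were false. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9. Of the 201 named genes 37 are overlapped on the opposite strand by another tested gene. Histone, vitellogenin, F-box, skr and sdz genes have near-identical copies between which reads may be split wrongly.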

Results

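Total RNA was profiled from whole hermaphrodites of the C. elegans wild-type strain N2, at a stage the labels place between the last larval stage (L4) and adults not yet fertile. The control libraries nevertheless held transcripts of early zygotic embryo genes, given below, so this stage may not hold for the control animals. Animals were fed bacteria carrying a control RNAi construct (3 libraries) or one against fars-1 (3 libraries) at 20 °C. The growth label names HT115, the usual RNAi feeding strain, whereas the extraction label names OP50. The gene fars-1 encodes a subunit of the cytosolic phenylalanyl-tRNA synthetase, the enzyme that loads phenylalanine onto its tRNA. The series title ties this enzyme to lifespan, immunity and double-stranded RNA made from the mitochondrial genome, so the comparison asks how the transcriptome of the animals differs after fars-1 RNAi. Total expected counts were 30866873, 33393180.0 and 34307717 in control libraries 1, 2 and 3, and 27362725, 32134888 and 25889448 in the libraries labelled fars-1 RNAi 1, 2 and 3. Below, levels are CPM (counts scaled to a common library size, with TMM normalisation) as mean ± SD with n = 3 per group, and log2 fold changes are the libraries labelled fars-1 RNAi over control RNAi, ± SE. The labels do not say plainly that the 3 libraries of a group came from separate cultures, so p-values may not measure spread between cultures. Libraries of a group did differ by more than counting error. The chi-square per degree of freedom between pairs of them was 11.39 to 77.17, where counting error gives about 1. Gene counts are given over all genes tested, and adjusted over the list alone they were the same unless stated. List sizes are of members that passed the low-count filter. These were 121 of 240 C-type lectin, 29 of 38 intracellular pathogen response and 19 of 30 epidermal antimicrobial peptide genes, for example. List members named as exceptions, and paralogues or kinases set beside a list, were chosen after their values were seen.

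The fars-1 transcript was higher, not lower, in the libraries labelled fars-1 RNAi. Its gene (WBGene00001497; WBcel235 chromosome I, 6211981 to 6214685, minus strand, counted over its exons) had 208, 206 and 201 CPM in the control libraries. It had 1618, 1394 and 3079 CPM in the libraries labelled fars-1 RNAi. The difference was 3.31 ± 0.29 on the log2 scale, a 9.90-fold rise (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.99e-05). The target transcript therefore goes against the label, and every direction given here rests on the labels as deposited. Reads of the fed double-stranded RNA would be counted with the gene, no other tested gene overlaps it, and the strand setting is not given in the sources used here. The partner subunit fars-3 had 211 ± 11.79 CPM in control and 188 ± 9.16 CPM in the libraries labelled fars-1 RNAi, a log2 difference of -0.17 ± 0.08 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0733), which was -0.36 with RLE, 0.39 with upper-quartile scaling, -0.39 with DESeq2 and -0.24 without control RNAi replicate 1, each then past the threshold. The mitochondrial enzyme fars-2 fell by 0.90 ± 0.07.

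**Figure D1:**
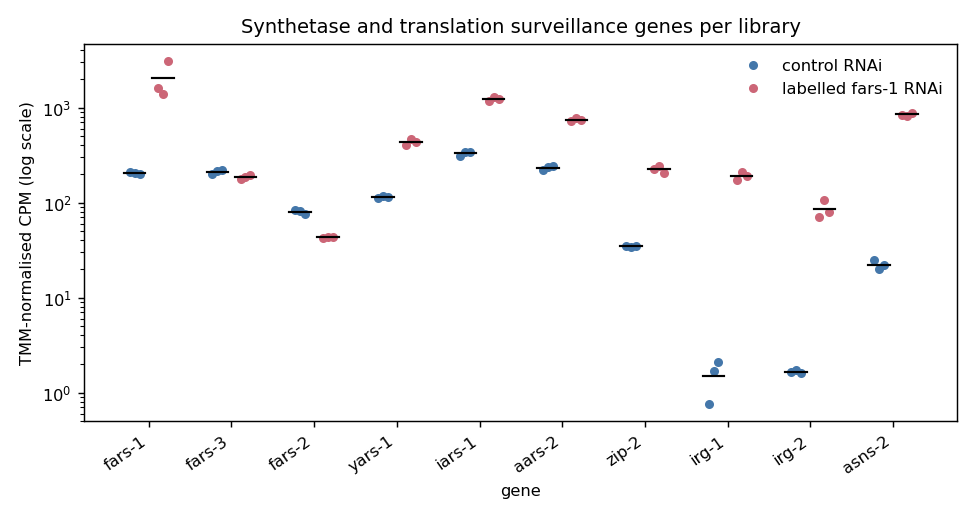
TMM-normalised CPM (y axis, log scale) of 10 genes (x axis) in each library; points are the 3 control RNAi libraries (blue) and the 3 libraries labelled fars-1 RNAi (red), and black lines are group means. fars-1 lies between 1394 and 3079 CPM in the libraries labelled fars-1 RNAi and between 201 and 208 CPM in control.

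Most measured genes differed between the groups. Of 15959 genes tested, 13368 (83.8%) passed at an adjusted p below 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), with 7112 higher and 6256 lower in the libraries labelled fars-1 RNAi, or 9030.0 and 4435 with upper-quartile scaling. At least 2-fold changes were called for 5379 genes higher and 4070 lower, or 4716 and 4724 with RLE and 7190.0 and 2486 with upper-quartile scaling. At least 4-fold changes were called for 2074 genes higher and 1701 lower. The libraries of the groups did not overlap for 13803 genes (86.5%), where chance alone gives 10%. Spearman correlations across genes were 0.980 to 0.992 among control libraries, 0.990 to 0.994 among those labelled fars-1 RNAi and 0.794 to 0.855 between groups. With so many genes moving, the zero point depended on scaling: the median log2 fold change over all genes was 0.21 with TMM, 0.02 with RLE, 0.77 with upper-quartile and 0.34 with total-count scaling. Genes higher made up 53.2% of calls with TMM, 48.9% with RLE and 67.1% with upper-quartile scaling, so changes much smaller than these shifts have no firm direction.

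The 12 genes with the largest rises belonged to several families. parg-2, a poly(ADP-ribose) glycohydrolase, rose from 1.11 ± 0.365 to 953 ± 135 CPM, and cng-1, a cyclic nucleotide-gated channel subunit, from 1.48 ± 0.444 to 575 ± 61.2 CPM. The cuticle collagen col-176 rose from 1.27 ± 0.726 to 910 ± 118 CPM and the C-type lectin clec-47 from 1.93 ± 0.876 to 664 ± 84.8 CPM. The ABC transporter pgp-7 rose by 7.83 ± 0.23, C04A11.5 by 8.01 ± 0.20 and C49G7.12 by 7.75 ± 0.17 on the log2 scale, and C25F9.11 from 0.122 ± 0.0774 to 76.7 ± 16.8 CPM. A further 4 rises started from 10 or fewer control counts in all. The pooled ratio was 529-fold for fipr-24 (95% exact interval 146 to 4374), 429-fold for clec-60 (233 to 896), 359-fold for ugt-18 (181.7 to 832) and 285.5-fold for the lysozyme ilys-3 (131 to 779). For clec-60 the log2 fold change was 8.69, and 11.05 without control RNAi replicate 3. In the edgeR quasi-likelihood test these 12 genes had Benjamini-Hochberg adjusted p of at most 2.21e-06.

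The 12 genes with the largest falls included acdh-1 and, from the early zygotic list, sdz-28 and pes-10. acdh-1, the acyl-CoA dehydrogenase of the propionate shunt, had 328 ± 111.5 CPM in control and 0.0621 ± 0.0781 CPM in the libraries labelled fars-1 RNAi, where 6 counts remained against 30496. Its log2 fold change was -12.17 ± 0.53, and -13.85 without fars-1 RNAi replicate 2. In 6 further genes 1 count was left in the libraries labelled fars-1 RNAi. The pooled ratio of control over these libraries was 2746 for the Skp1-related skr-7 (95% exact interval 493 to 108500), 1865 for clec-222 (334 to 73690), 1764 for sdz-28 (316 to 69720), 1456 for skr-8 (261 to 57530), 1017 for pes-10 (182.1 to 40190) and 954 for E02H9.7 (171 to 37700). For B0281.5, with 3 counts left, it was 812 (278 to 3941). sdz-30, sepa-1 and a pes-2.1 copy (WBGene00010158) had 5, 6 and 4 counts left against 3142, 3743 and 5270 in control, and Y57G11B.5 went from 181.3 ± 64.3 to 0.327 ± 0.515 CPM. Fitted log2 values of these genes moved when fars-1 RNAi replicate 1 was left out: from -11.001 to -12.93 for skr-7, -10.45 to -12.39 for clec-222, -10.37 to -12.297 for sdz-28, -10.11 to -12.04 for skr-8, -9.56 to -11.50 for pes-10 and -9.46 to -11.39 for E02H9.7. They moved from -9.53 to -12.76 for B0281.5, -9.13 to -13.04 for sdz-30, -9.12 to -13.28 for sepa-1 and -9.14 to -12.27 for Y57G11B.5. The intervals of the ratios cover counting error only. The 12 genes had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of at most 6.72e-06.

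Genes of the female germline, the oocyte and the embryo were lower together in the libraries labelled fars-1 RNAi. All 50 germline proliferation and meiosis genes tested fell, or 46 with upper-quartile scaling (median log2 fold change -1.74 with TMM), among them zim-1 (-2.48 ± 0.10), deps-1 (-2.29 ± 0.10) and gld-3 (-2.63 ± 0.13). Of 36 oocyte and eggshell genes 35 fell and pqn-65 did not pass (median -3.34), with the translational regulators puf-11 at -3.48 ± 0.15, cey-3 at -2.98 ± 0.14 and cey-2 at -3.05 ± 0.15. Of 18 early zygotic genes 16 fell, while the transcription factor genes elt-7 and nob-1 rose (median -3.22, also with genes at 0 set to their bound), and vet-6 went from 33.9 ± 6.92 to 0.104 ± 0.0412 CPM. All 6 vitellogenin genes, which encode yolk proteins, fell (median -4.13). vit-1 fell from 2918 ± 625 to 120 ± 29.8 CPM, vit-3 from 5701 ± 1337 to 105 ± 53.3 CPM and vit-4 from 5468 ± 1191 to 66.98 ± 45.4 CPM. For vit-4 the log2 fold change was -6.35, and -7.07 without fars-1 RNAi replicate 1. Reads of near-identical copies such as the vitellogenins could have been split between genes. In camera, a test of a list against all other genes, the Benjamini-Hochberg adjusted p was 7.16e-12 for germline, 2.01e-10 for oocyte, 2.91e-04 for early zygotic genes and 7.59e-03 for vitellogenins. The adjusted p = 0.498, 0.581, 0.498 and 0.587 with an estimated correlation, in the same order.

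Genes for cell division and chromatin were lower as well. Of 61 cell cycle and DNA replication genes 60 fell (median -2.15), with cdc-25.3 at -5.91 ± 0.20, the condensin subunit capg-2 at -2.95 ± 0.10 and the replicative helicase subunit mcm-5 at -2.65 ± 0.09, while the cell cycle inhibitor cki-1 rose. Of 69 histone genes 60 fell, 6 rose (hil-1, his-35, his-37, his-41, his-70, his-71) and 3 did not pass (median -2.53), with his-4 at -3.97 ± 0.10 and his-3 at -3.36 ± 0.09. Histone genes are near-identical copies, so single values are uncertain. The summed share of all counts was taken over every gene with a his- name, tested or not, and without hil genes. It was 1.71% ± 0.0910 in control and 0.378% ± 0.0209 in the libraries labelled fars-1 RNAi (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). All 33 proteasome subunit genes fell with TMM and RLE scaling, more modestly (median -1.04 with TMM), while with upper-quartile scaling 23 fell and 2 rose (median -0.48). Among them were rpn-9 at -1.26 ± 0.07 and pbs-6 at -1.16 ± 0.07. The camera adjusted p (Benjamini-Hochberg) was 8.37e-15 for cell cycle, 7.16e-12 for histone and 9.6e-08 for proteasome genes. For each of the 3 lists the adjusted p = 0.498 with an estimated correlation.

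Moulting genes and markers of somatic tissues were higher. Of 48 moulting and larval cuticle genes 39 rose, 5 fell (mlt-7, dpy-14, dpy-17, grd-3, bli-5) and 4 did not pass (median 2.503), with ptr-4 at 5.28 ± 0.22 and the furrow collagens dpy-9 and dpy-7 at 3.87 ± 0.22 and 3.76 ± 0.22. Of 36 muscle markers 35 rose and hlh-1 did not pass (median 1.31), with ttn-1 and unc-89 both at 2.64 ± 0.17 and unc-22 at 2.67 ± 0.18. Of 43 neuronal markers 38 rose, tdc-1, bas-1 and unc-119 fell and tax-2 and tax-4 did not pass (median 1.37), with ida-1 at 2.33 ± 0.09 and egl-3 at 2.13 ± 0.09. Neuropeptide and insulin genes rose in 45 of 53 cases, 2 fell (ins-2, ins-34) and 6 did not pass (median 1.33), with flp-15 at 2.401 ± 0.19. Hypodermis markers rose in 19 of 24 cases, elt-1 and lin-26 fell and 3 did not pass (median 1.17), with mua-3 at 2.42 ± 0.11; adjusted over the list alone 19 rose and 3 fell. Benjamini-Hochberg adjusted p from camera was 3.82e-05 for moulting, 1.06e-06 for muscle, 2.09e-06 for both neuronal lists and 1.22e-03 for hypodermis. The adjusted p = 0.582 for moulting, 0.587 for muscle and 0.498 for the other 3 lists with an estimated correlation.

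Sperm genes did not follow the oocyte genes. Of 62 tested, 32 rose, spe-39, spe-44 and ife-3 fell and 27 did not pass (median 0.79), and adjusted over the list alone 29 rose and 3 fell. With upper-quartile scaling 50 rose and 2 fell. fer-1, needed for membrane fusion in spermatids, rose by 3.69 ± 0.39, and by 4.32 without control RNAi replicate 3. Adult cuticle collagens were lower for 11 of 20 genes and higher for 4 (col-38, bli-1, bli-2, col-144), with 5 not passing (median -1.68). col-140 was at -5.53 ± 0.67 and col-143 at -5.29 ± 0.45, or -6.47 and -5.88 without fars-1 RNAi replicate 1, and col-144 at 4.69 ± 0.44, or 5.29 without control RNAi replicate 3. Libraries differed within groups. Control library 3 had a mean log2 level above the control mean by 0.63 for sperm, 0.45 for moulting and 0.74 for adult cuticle genes, and adult cuticle genes were at -0.64, -1.60 and -3.10 in libraries 1, 2 and 3 labelled fars-1 RNAi. As lists, the camera adjusted p (Benjamini-Hochberg) was 6.19e-03 for sperm genes and 0.264 for adult cuticle genes. With an estimated correlation the adjusted p = 0.767 and 0.821, and fry, a directional test of the list itself, gave 0.0784 for sperm genes.

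**Figure D2:**
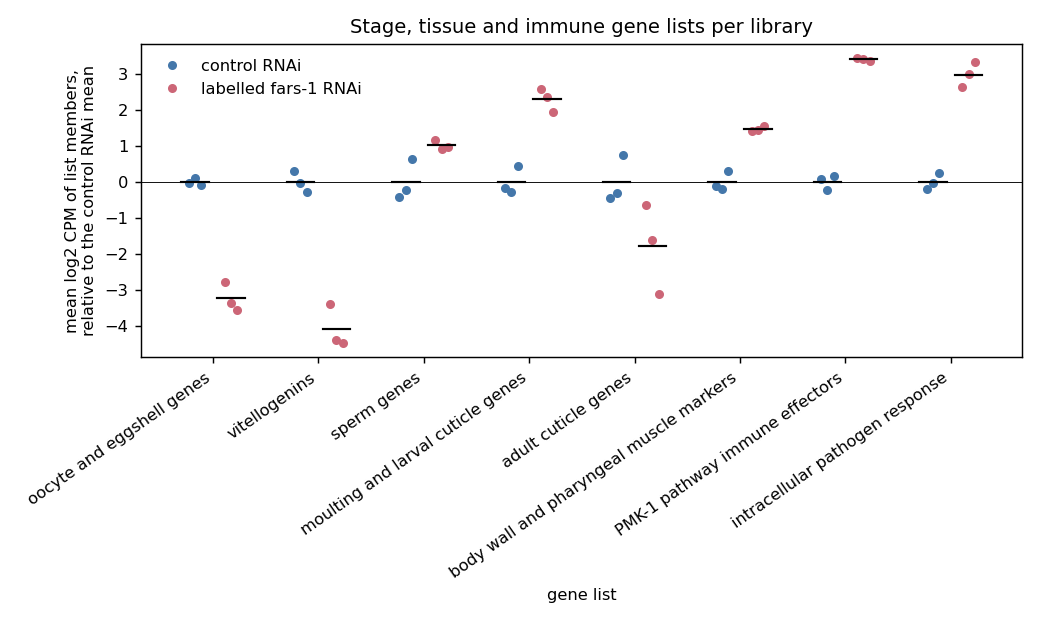
Mean log2 CPM of the tested members of 8 gene lists (x axis) in each library, relative to the mean of the control RNAi libraries (y axis, log2 units); points are libraries and black lines group means. Oocyte genes lie between -3.55 and -2.78 and intracellular pathogen response genes between 2.62 and 3.31 in the libraries labelled fars-1 RNAi.

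Immune genes were among the lists with the largest rises. Of 22 effectors of the PMK-1 p38 pathway, the main innate immune kinase cascade of the intestine, 20 rose, C32H11.4 fell and F55G11.8 did not pass (median 3.67). Among them rcd-1 rose by 6.98 ± 0.22, irg-4 by 5.53 ± 0.20 and hpo-6 by 3.77 ± 0.12. The intracellular pathogen response, a gene set induced by microsporidia and virus, rose for 28 of 29 genes (median 3.00), with pals-4 not passing. The ubiquitin ligase components skr-3 and skr-4 of this set rose by 3.00 ± 0.12 and 2.11 ± 0.11. Components of the p38 pathway rose in 17 of 24 cases, skn-1, cebp-2, dkf-2, dcap-1 and nhr-86 fell and atf-7 and mek-1 did not pass (median 1.09), with the phosphatase vhp-1 at 3.16 ± 0.09 and the upstream adaptor tir-1 at 2.81 ± 0.09. The median of these components was below those of muscle, neuronal and hypodermis markers (1.31, 1.37 and 1.17). The kinase genes sek-1 and pmk-1 were at 0.80 ± 0.11 and 0.56 ± 0.10, and the transcription factor atf-7 was at -0.05 ± 0.08, or 0.51 with upper-quartile scaling. In camera the Benjamini-Hochberg adjusted p was 6.34e-06 for effectors, 1.92e-06 for the pathogen response and 0.0159 for pathway components. The adjusted p = 0.498, 0.498 and 0.581 with an estimated correlation.

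Antimicrobial families rose in part. Of 121 C-type lectin genes 67 rose, 28 fell and 26 did not pass (median 0.98), with clec-265 at 4.96 ± 0.16, clec-41 at 2.72 ± 0.10 and clec-223 at -7.43 ± 0.20. Of 19 epidermal antimicrobial peptide genes 14 rose, nlp-27 and nlp-28 fell and 3 did not pass (median 1.32), with cnc-4 at 5.51 ± 0.22 and nlp-29 at 2.60 ± 0.16. Medians of muscle, neuronal and hypodermis markers were 1.31, 1.37 and 1.17, above that of the lectins and near that of the epidermal peptides. Lysozyme genes rose in 8 of 11 cases and lys-4, lys-6 and ilys-5 fell (median 1.91), with lys-2 at 3.57 ± 0.16. Of 23 saposin-like and thaumatin genes 5 were higher, 6 lower and 12 not passing with TMM scaling, against 14 higher and 2 lower with upper-quartile scaling, and spp-4 was at -2.96 ± 0.14. Their median was 0.10 with TMM, -0.10 with RLE and 0.67 with upper-quartile scaling, their mean 0.17 with TMM, where camera put the list down. The camera adjusted p (Benjamini-Hochberg) was 0.0304 for lectins (0.0846 with upper-quartile scaling; 0.0207 to 0.587 over 14 alternatives within camera), 0.0116 for epidermal peptides, 0.0908 for lysozymes and 0.967 for saposins. The adjusted p = 0.587 for lectins and 0.581 for epidermal peptides with an estimated correlation.

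Genes that respond to blocked translation were higher, while the synthetase genes did not pass as a list. Of 10 genes of the ZIP-2 surveillance list 9 rose and cebp-2 fell (median 2.79). irg-1 rose from 1.502 ± 0.676 to 189 ± 18.4 CPM, irg-2 from 1.66 ± 0.0754 to 85.8 ± 19.4 CPM, and their regulator zip-2 from 34.7 ± 0.588 to 223 ± 18.1 CPM. Benjamini-Hochberg adjusted p from camera was 4.81e-03, and the adjusted p = 0.498 with an estimated correlation. Apart from fars-1, 10 of 31 aminoacyl-tRNA synthetase genes rose, 16 fell and 5 did not pass, or 16 rose and 6 fell with upper-quartile scaling (median -0.26 with TMM and 0.29 with upper-quartile scaling; camera Benjamini-Hochberg adjusted p = 0.411). The rises were led by yars-1 (1.94 ± 0.08), sars-1 (1.90 ± 0.10), iars-1 (1.89 ± 0.09) and aars-2 (1.67 ± 0.08). Names ending in -2, which often mark mitochondrial enzymes, were split off after the values were seen: 10 of these 11 genes fell and aars-2 rose, and of the other 20 genes 9 rose and 6 fell (medians -0.78 and 0.14, with TMM scaling). With aars-1 exchanged for aars-2, a choice that rests on no table here, 11 of 11 fell, and of the other 20 genes 10 rose and 5 fell (medians -0.79 and 0.32). Genes of the ATF-4 amino acid starvation response went both ways, with 10 higher, 9 lower and 5 not passing, or 15 higher and 5 lower with upper-quartile scaling. asns-2, an asparagine synthetase, rose from 22.1 ± 2.52 to 846 ± 25.6 CPM, and the glutamine synthetase gln-6 fell by 3.16 ± 0.18. The list's median was -0.03 and its mean 0.22, or a median of 0.52 with upper-quartile and 0.08 with total-count scaling. Camera put it down (Benjamini-Hochberg adjusted p = 0.994) and fry up (adjusted p = 0.00285; 0.00285 to 0.996 over its 15 alternatives), so its direction was not settled.

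Other parts of the translation machinery had medians near that of all genes. Of 83 cytosolic ribosomal protein genes 55 rose, 5 fell (rpl-11.1, rpl-25.2, rpl-29, rpl-41.1, rpl-41.2) and 23 did not pass, with a median of 0.34, close to the all-gene median of 0.21. With RLE scaling 27 rose and 7 fell, and with upper-quartile scaling 77 rose and 2 fell (median 0.90). The camera adjusted p (Benjamini-Hochberg) of 1.22e-03 became 0.0984 with RLE scaling, where the median was 0.15, and adjusted p = 0.67 with an estimated correlation (1.09e-05 to 0.67 over 14 alternatives within camera). The paralogues rpl-11.2 and rpl-11.1 moved apart, at 1.92 ± 0.13 and -1.43 ± 0.11, and rpl-25.1 was at 2.00 ± 0.10. Of 43 translation factor genes 12 rose and 20 fell, with the elongation factor eef-1A.2 at 3.09 ± 0.13 and its paralogue eef-1A.1 at 0.28 ± 0.10, a value that did not pass with RLE scaling (0.08), no filter (0.25), the replicate block (0.28) or DESeq2 (0.06), or without control RNAi replicate 2 (0.29), fars-1 RNAi replicate 1 (0.31), 2 (0.25) or 3 (0.27). Of 31 nucleolar and ribosome biogenesis genes 9 rose and 13 fell, with ruvb-2 at -1.62 ± 0.08. Adjusted over the list alone 12 and 19 translation factor genes and 8 and 13 nucleolar genes were higher and lower. With upper-quartile scaling the balance reversed, to 27 and 8 translation factor genes and 19 and 8 nucleolar genes. Medians of these last lists were -0.12 and -0.13 with TMM and 0.44 and 0.43 with upper-quartile scaling (camera Benjamini-Hochberg adjusted p = 0.559 and 0.329).

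Mitochondrially encoded transcripts differed little. Of the 12 mRNAs of the mitochondrial genome 5 were lower, 0 higher and 7 did not pass (median -0.37), and adjusted over the list alone 2 were lower. With RLE scaling 8 were lower and 0 higher, with total counts 2 and 0, and with upper-quartile scaling 0 lower and 2 higher. nduo-4 went from 1302 ± 297 to 769 ± 58.95 CPM (-0.76 ± 0.16), ctb-1 from 4719 ± 1012 to 2923 ± 187 CPM (-0.69 ± 0.16), nduo-1 was at -0.41 ± 0.14, nduo-6 at -0.70 ± 0.26 and ndfl-4 at -1.35 ± 0.53 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00263, 0.0037, 0.0262, 0.0364 and 0.0435). nduo-1 did not pass without fars-1 RNAi replicate 1 (-0.37) or 2 (-0.41), nduo-6 without control RNAi replicate 1 (-0.40) or fars-1 RNAi replicate 1 (-0.54) or 3 (-0.75), and ndfl-4 without control RNAi replicate 1 (-0.87) or fars-1 RNAi replicate 1 (-1.02) or 2 (-1.31). These 3 also did not pass with total counts (-0.28, -0.56 and -1.21) or the replicate block (-0.39, -0.66 and -1.29), nduo-1 and nduo-6 with limma on log2(TPM + 1) (-0.20 and -0.46), and nduo-6 at CPM of at least 1 (-0.64). ctc-1 at -0.03 ± 0.14 and the ribosomal RNAs MTCE.7 at -0.04 ± 0.20 and MTCE.33 at -0.03 ± 0.19 did not pass with TMM, but with upper-quartile scaling they were at 0.53, 0.53 and 0.54 and passed as higher, as did ctc-3 at 0.56. With that scaling the list's median was 0.19, nduo-1 was at 0.15, and nduo-4, ctb-1, nduo-6 and ndfl-4 did not pass. For the list the camera adjusted p (Benjamini-Hochberg) was 0.194. Mitochondrial genes took 11.3% ± 2.23 of counts in control and 11.82% ± 0.469 in the libraries labelled fars-1 RNAi (exact two-sided permutation p = 0.7). Gene counts without a stated strand setting cannot separate sense from antisense RNA, so double-stranded RNA was not measured.

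**Figure D3:**
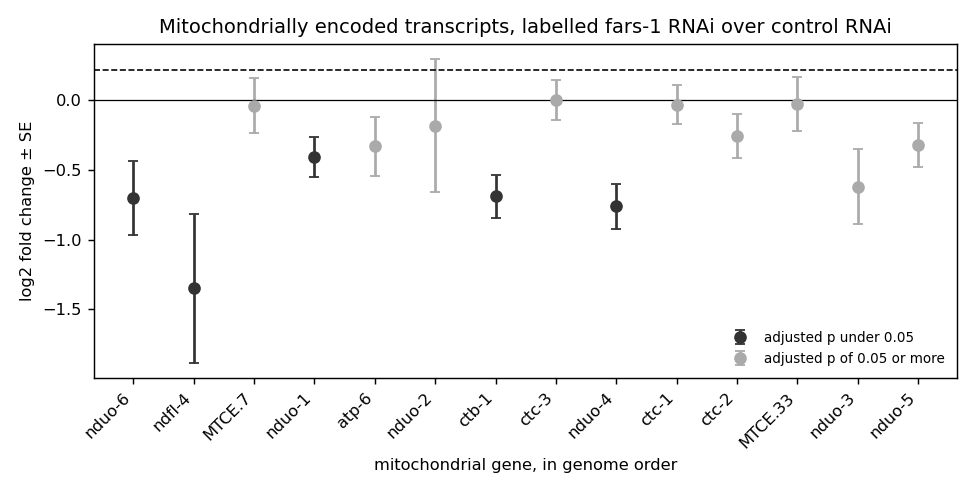
Log2 fold change ± SE (y axis) of the 12 mRNAs and 2 ribosomal RNAs of the mitochondrial genome in genome order (x axis), libraries labelled fars-1 RNAi over control RNAi with TMM scaling; dark points passed the test, grey ones did not, and the dashed line marks the all-gene median of 0.21. The 5 genes that passed lie between -1.35 and -0.41; with upper-quartile scaling none of them is called lower and nduo-1 is at 0.15.

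Nuclear genes for mitochondrial translation were lower. Of 70 mitochondrial ribosomal protein genes 67 fell, mrpl-37 rose and mrpl-22 and mrpl-41 did not pass (median -0.93), or 41 fell and 4 rose with upper-quartile scaling (median -0.37). The falls included mrpl-45 at -1.49 ± 0.10, mrpl-39 at -1.31 ± 0.08 and mrps-22 at -1.14 ± 0.08. In camera the Benjamini-Hochberg adjusted p was 5.76e-09, and the adjusted p = 0.581 with an estimated correlation. The germline and cell cycle lists were lower too (medians -1.74 and -2.15). Genes for mitochondrial DNA and RNA upkeep were lower in 6 of 10 cases and higher for rpom-1 and twnk-1, or 4 and 4 with upper-quartile scaling (median -0.68 with TMM; camera Benjamini-Hochberg adjusted p = 0.196), with the DNA packaging gene hmg-5 at -1.78 ± 0.12. Of 38 nuclear genes for respiratory chain subunits 18 fell, 5 rose (sdha-1, ucr-2.1, ucr-2.2, asb-2, asg-2) and 15 did not pass, a balance that reversed to 22 higher and 6 lower with upper-quartile scaling. The falls were led by asb-1 (-2.45 ± 0.11), ucr-2.3 (-1.88 ± 0.10) and sdha-2 (-1.70 ± 0.10), each the paralogue of a gene that rose. That list had a median of -0.13 with TMM and 0.43 with upper-quartile scaling. Its camera adjusted p (Benjamini-Hochberg) was 0.137, but 0.0228 with RLE scaling and 0.0457 without control RNAi replicate 1 (0.0228 to 0.944 over 14 alternatives within camera). The mitochondrial unfolded protein response list had 6 genes higher, 10 lower and 4 not passing (median -0.26), or 9 higher and 2 lower with upper-quartile scaling (median 0.30; camera Benjamini-Hochberg adjusted p = 0.455). The mitochondrial chaperones hsp-6 and hsp-60 were at -0.60 ± 0.08 and -0.77 ± 0.08, or -0.05 and -0.22 and not past the threshold with upper-quartile scaling, while dve-1 rose from 5.57 ± 0.233 to 14.7 ± 1.68 CPM.

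The RNA interference machinery was lower. Of 55 genes 44 fell, 6 rose and 5 (rde-12, sid-5, sago-1, sago-2, xrn-2) did not pass (median -1.07). rde-4, the double-stranded RNA-binding partner of Dicer, fell by 2.38 ± 0.09, the microprocessor subunit pash-1 fell by 1.92 ± 0.09 and mut-2 was at -2.702 ± 0.12. The systemic RNAi channel sid-1 fell by 1.19 ± 0.10, rde-1 by 1.05 ± 0.12 and dcr-1 by 0.69 ± 0.13, the last at -0.14 and not past the threshold with upper-quartile scaling. sid-2, the intestinal receptor for ingested double-stranded RNA, rose by 2.09 ± 0.12, and sid-3, rrf-2, alg-1 and the sperm Argonautes alg-3 and alg-4 rose as well. The RIG-I-like helicase drh-1 was at -0.50 ± 0.10, or at 0.05 with upper-quartile scaling and -0.29 with limma on log2(TPM + 1), neither past the threshold. The camera adjusted p (Benjamini-Hochberg) was 1.06e-06, and the adjusted p = 0.55 with an estimated correlation. Many of these genes act in the germline, whose own list was also lower (median -1.74).

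Detoxification genes were higher as lists. Of 63 cytochrome P450 genes 39 rose, 12 fell and 12 did not pass (median 1.05), with cyp-14A5 at 4.798 ± 0.12 and cyp-31A2 at -3.49 ± 0.10. Of 63 UDP-glucuronosyltransferase genes 40 rose, 13 fell and 10 did not pass (median 1.01), with ugt-29 at 4.24 ± 0.10. Benjamini-Hochberg adjusted p from camera was 7.29e-03 and 9.64e-03, and for both the adjusted p = 0.498 with an estimated correlation. Muscle, neuronal and hypodermis markers rose by more (medians 1.31, 1.37 and 1.17). Of 34 SKN-1 and glutathione genes 12 were higher, 13 lower and 9 not passing with TMM scaling, against 24 higher and 5 lower with upper-quartile scaling, with gst-24 at 4.19 ± 0.12 and gst-7 at -2.22 ± 0.09. Their median was 0.10 with TMM, -0.09 with RLE and 0.66 with upper-quartile scaling (camera Benjamini-Hochberg adjusted p = 0.828).

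Genes linked to longevity signalling and protein stress went both ways. Targets that the insulin-pathway factor DAF-16 activates were higher in 18 of 26 cases and lower in 6 (median 0.76), with ftn-1 at 3.98 ± 0.22, lea-1 at 1.19 ± 0.07 and lys-7 at 1.70 ± 0.13. Targets it represses were also higher in 12 of 19 cases and lower in 5, or 13 and 5 adjusted over the list alone (median 1.44), with dod-22 at 4.78 ± 0.21. As lists, the camera adjusted p (Benjamini-Hochberg) was 0.128 and 0.118. Cytosolic heat shock genes had 5 higher and 9 lower of 16 (median -0.38), or 6 and 3 with upper-quartile scaling (median 0.17), with hsp-17 at 2.18 ± 0.14 and sip-1 at -2.76 ± 0.22. The endoplasmic reticulum stress list had 11 higher and 18 lower of 34, or 11 and 19 adjusted over the list alone (median -0.26), and 18 and 9 with upper-quartile scaling (median 0.29), with hsp-4 at -1.09 ± 0.08. The autophagy and lysosome list had 17 higher and 21 lower of 50, or 16 and 21 adjusted over the list alone (median -0.07, or 0.06 with total-count scaling), and 30 and 14 with upper-quartile scaling (median 0.49), with sqst-1 at 2.82 ± 0.09 and vha-7 at -1.95 ± 0.10. In camera the Benjamini-Hochberg adjusted p was 0.411, 0.264 and 0.363 for these 3 lists.

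Metabolic genes and the remaining families did not pass as lists. Phenylalanine and tyrosine catabolism had 8 genes higher, pcbd-1 and tdc-1 lower and 3 not passing of 13, or 5 higher and 3 lower with RLE scaling (median 0.28 with TMM), with tatn-1 at 1.78 ± 0.14, hpd-1 at 0.78 ± 0.07 and tdc-1 at -3.23 ± 0.16. Amino acid transporters had 14 higher and 7 lower of 23, or 15 and 7 adjusted over the list alone (median 0.75), with aat-2 at 2.64 ± 0.15. Lipid breakdown and propionate genes had 13 higher and 20 lower of 42 (median -0.26), or 21 and 16 with upper-quartile scaling (median 0.29), with ech-6 at -1.77 ± 0.10. Fatty acid synthesis genes had 13 higher and 13 lower of 28 (median 0.14, or -0.06 with RLE scaling; mean -0.10, and down in camera), with sbp-1 at 2.12 ± 0.10. Digestive protease and intestine genes had 18 higher and 9 lower of 29, or 19 and 9 adjusted over the list alone (median 0.82), with cpr-3 at 3.75 ± 0.13. The camera adjusted p (Benjamini-Hochberg) was 0.302, 0.232, 0.131, 0.805 and 0.163 in that order. Collagens as a whole had 50 higher, 36 lower and 35 not passing of 121, or 48 and 36 adjusted over the list alone (median 0.57, mean 0.03; adjusted p = 0.73), with col-101 at -4.62 ± 0.15. The coelomocyte, gonad sheath and spermatheca list had 8 higher and 8 lower of 18 (median 0.22, mean -0.33, down in camera; adjusted p = 0.78), with the gonad innexin inx-8 at -4.17 ± 0.14. The F-box and MATH/BATH list had 114 higher, 23 not passing and the rest of 279 lower, with 1 more lower adjusted over the list alone (median -0.75; adjusted p = 0.128), with fbxa-37 at 3.84 ± 0.13. These last 3 p-values are also from camera with Benjamini-Hochberg adjustment. The F-box list passed as lower with upper-quartile scaling (2.12e-03, and 2.12e-03 to 0.767 over 14 alternatives within camera). Its median there was -0.19, below the all-gene median of 0.77, as its TMM median was below the all-gene 0.21. The list pools fbxa genes (median 1.601) with fbxb genes (median -7.40), which moved in opposite directions, so its pooled median and p say little about either.

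**Figure D4:**
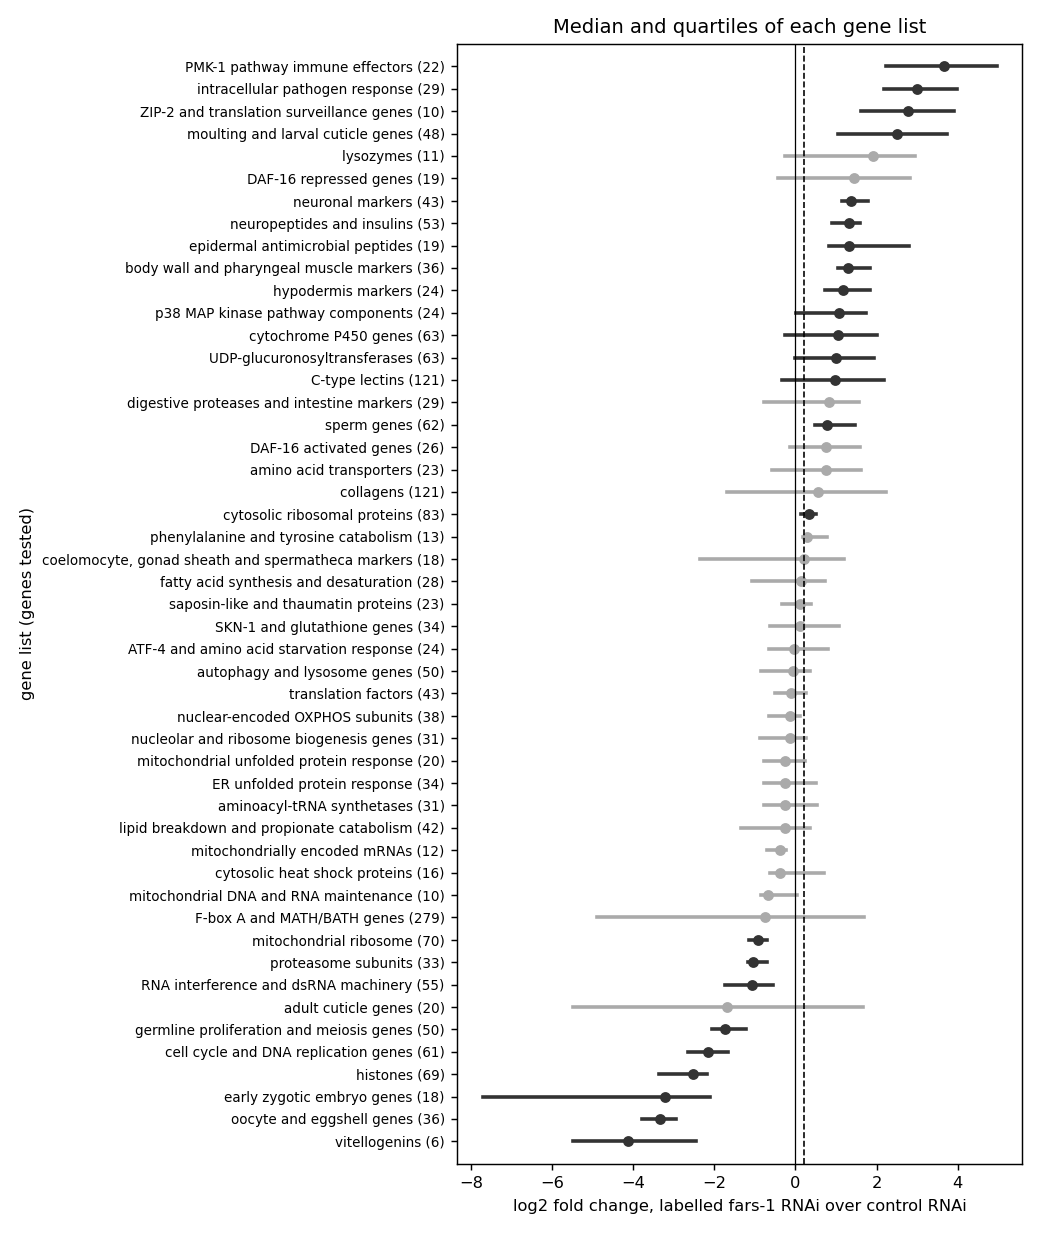
Log2 fold change of the libraries labelled fars-1 RNAi over control RNAi (x axis) for 49 gene lists (y axis, genes tested in brackets); points are medians and bars the quartiles over the list's genes, dark where camera passed with the preset correlation and grey where it did not. The solid line is 0 and the dashed line the all-gene median of 0.21 with TMM scaling; list medians run from -4.13 for vitellogenins to 3.67 for PMK-1 effectors.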

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

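The fit without mitochondrial genes, and list tests with upper-quartile and total-count scaling, were chosen after seeing the data; the other alternatives were planned. The fars-1 transcript stayed higher and past the threshold in all 16 alternatives run on it, with log2 fold changes from 2.87 to 3.52 when each library was left out in turn and 3.21 with the replicate block. Genes called numbered 13057 with RLE, 13465 with upper-quartile, 13291 with total-count scaling, 12880.0 with DESeq2, 13498 with limma-voom, 12008 with limma on log2(TPM + 1), 14000 with no filter, 12172 at CPM of at least 1, 13043 with the replicate block and 13367 without mitochondrial genes. Leaving out each library gave 12621 to 13736 genes, 9104 to 10129 at least 2-fold changed genes and 24 to 25 lists. Tested against a 2-fold change, 7150 genes passed, since that test asks for more than a difference.

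Of 49 lists, camera with an estimated correlation called 0 (3 at an unadjusted p under 0.05), the preset correlation 24 and fry 41. Of the 24 lists fry called 23. Lists passed by fry but not by camera included lysozymes (fry adjusted p = 7.34e-05, up) and DAF-16 activated genes (5.12e-04, up). Others were amino acid transporters (0.00104, up), respiratory chain subunits (7.99e-04, down) and lipid breakdown genes (5.57e-04, down). Fry does not compare a list with other genes. The estimated correlations had a median of 0.149, against the preset 0.01. For the ZIP-2 list the estimate was -0.00884, below the preset, yet its unadjusted camera p went from 0.00167 to 0.0304. A larger correlation thus does not account for the loss of that list. The estimated version takes its degrees of freedom from the 6 libraries, not from the genes, which raises p without a larger correlation. How far this, rather than larger estimated correlations, explains the loss of the other lists was not tested. Over 15 alternatives and 49 lists, 686 outcomes were the same, 27 weaker, 20 stronger and 1 reversed: the ATF-4 list was up in fry with adjusted p = 0.00285 (range over its alternatives 0.00285 to 0.996, within camera 0.578 to 0.996). Upper-quartile scaling lost the lectin call (0.0846) and gained the F-box one (0.00212). The camera direction turned for 8 lists with upper-quartile, 2 with total-count and 1 with RLE scaling, 0 of them called with TMM or that scaling. Of the outcomes for named genes 3138 were the same, 40 weaker, 3 stronger and 9 reversed. The reversed ones all came from upper-quartile scaling, where log2 fold changes were 0.15 for nduo-1, 0.39 for fars-3, 0.33 for alh-8, 0.51 for atf-7, 0.0517 for drh-1, 0.53 for MTCE.7, 0.54 for MTCE.33, 0.53 for ctc-1 and 0.56 for ctc-3. That scaling moves the all-gene median from 0.21 to 0.77, by more than these genes' values with TMM; the cause of the difference between scalings was not tested.

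Replicate numbers do not pair the libraries: deviations from the group mean of control and fars-1 RNAi libraries with the same number correlated across genes at -0.0315, -0.0136 and 0.00424. The planned fit with effective lengths as offsets was not run, as the files lack them. In simulated libraries of this depth 30% of 1.5-fold and 74% of 2-fold changes were found. There 50 genes per fold were changed, far fewer than here, so the adjusted threshold was stricter and these rates do not carry over.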

Other observations

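The families in this part were chosen after their values were seen, and so were all tests in it except those of vitamin B12 supply and acdh-2. Among 141 families of at least 10 genes with a shared name prefix, 77 passed camera with the preset correlation (42 up, 35 down) and 0 with an estimated one. Of 91 fbxb genes, an F-box family, 88 were lower and 1 higher, with a median log2 fold change of -7.40, or -5.13 with the 43 genes at 0 in a group set to their bound. Of 28 sdz genes, expressed under the embryonic regulator SKN-1, 25 were lower and 3 higher (median -6.69, or -5.28 with bounds). The related fbxa family went the other way, with 91 of 131 higher and 28 lower (median 1.601), although fbxa-215 fell by 3.71 ± 0.15. With TMM scaling all 14 pgp transporter genes tested rose (median 2.92), with pgp-5 from 28.1 ± 6.10 to 1656 ± 108 CPM and pgp-6 from 31.04 ± 14.7 to 5694 ± 337 CPM. Acyltransferase genes of the oac family rose in 29 of 34 cases (median 2.195), led by oac-7 at 6.44 ± 0.17 and oac-14 at 5.86 ± 0.24, and pals genes in 20 of 24 (median 2.37), with pals-24 at 3.83 ± 0.10. Of 194 nuclear hormone receptor genes 136 rose and 23 fell (median 0.95), the falls including nhr-2 (-6.40 ± 0.27) and nhr-68 (-2.77 ± 0.15). With TMM scaling all 26 nucleoporin genes (npp) fell (median -1.24), as did 19 of 20 Mediator genes (median -1.34) and 16 of 17 TAF genes (median -1.55). Germline proliferation and cell cycle lists fell more (medians -1.74 and -2.15), and the rise of nhr genes was below that of muscle, neuronal and hypodermis markers (1.31, 1.37 and 1.17). None of these 10 family directions changed with RLE, upper-quartile or total-count scaling. The camera adjusted p (Benjamini-Hochberg over families) was 1.89e-18 for fbxb, 3.1e-06 for sdz, 2.26e-04 for fbxa, 1.16e-04 for pgp, 8.83e-04 for oac, 9.41e-04 for pals, 2.54e-06 for nhr and npp, 1.71e-04 for Mediator and 1.14e-04 for TAF genes. With an estimated correlation it was 0.467 for fbxa, sdz and npp and 0.457 for the others.

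Genes on different chromosomes had different medians. The median log2 fold change was -0.25 for chromosome I, -0.03 for II, -0.20 for III, 0.28 for IV, 0.60 for V and 0.67 for X, with TMM scaling. With upper-quartile scaling chromosomes I, II and III were at 0.30, 0.53 and 0.36, and with total counts II was at 0.10, so the signs depend on scaling. On the X chromosome 56.1% of genes tested were higher and 24.1% lower, and on chromosome I 36.8% and 48.0%.

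The fars-1 transcript was higher in the libraries labelled fars-1 RNAi. An exchange of the group labels was weighed with the translation surveillance list, whose median log2 fold change was 2.79 in the libraries labelled fars-1 RNAi. An exchange was predicted to put it below 0. The list was used after it was seen to rise, and it shares zip-2 and cebp-2 with the p38 list. It rose together with the immune lists, for which other causes stay open, so it does not settle the labels. A joint rise of cytosolic synthetase genes as the source of the 3.31 is argued against by 20 other genes, those without a name ending in -2 but with aars-2 in place of aars-1, of which 5 fell, with a median of 0.32 (0.87 with upper-quartile scaling) and a highest value of 1.94. By name ending alone 6 fell and the median was 0.14 (0.70 with upper-quartile scaling). Reads of the fed double-stranded RNA counted as the gene stay open as a candidate explanation. The coefficient of variation of fars-1 in these libraries was 45.1%, at percentile 99.5 among the 400 genes nearest in level (median 4.66%), which carry-over differing between harvests could give. That spread rests on fars-1 RNAi replicate 3: without it the coefficient was 10.5%, at percentile 85.75.

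Oocyte, embryo and yolk genes were lower, and moulting, immune and pathogen response genes higher. Loss of the whole germline is argued against by the sperm list, with a median of 0.79 and 3 of 62 genes lower. That holds only in so far as its transcripts would fall with such a loss. In addition, 27 of the genes did not pass, and fry gave a Benjamini-Hochberg adjusted p of 0.0784, so the list alone does not exclude it. A smaller germline share that raises every somatic transcript alike was weighed with 51 immune members and 103 muscle, neuronal and hypodermis markers. Their medians were 3.06 and 1.33, a difference of 1.73. Both sets were picked after their medians were seen, so this difference was known in advance and decides nothing. It shows only that these immune lists rose by more than these markers. The digestive protease and intestine list, left out of the markers, had a median of 0.82. Genes are not independent, so the difference was taken per library: 1.43, 1.61 and 2.14 in the libraries labelled fars-1 RNAi, and 0.0479, -0.0605 and 0.0223 in control libraries 1, 2 and 3. An earlier stage of the animals may explain part of the pattern and stays open. Among early zygotic genes vet-6, sdz-28 and pes-10 were at 33.9, 20.2 and 11.6 CPM in control. In the libraries labelled fars-1 RNAi they were at 0.104, 0.0118 and 0.0118 CPM. Of the 18 genes of that list 16 fell and 2 rose. Control animals may thus have held embryos, against the stage given in the labels. Control library 3 minus 1 correlated across genes with the mean library labelled fars-1 RNAi minus control library 2 (Spearman 0.491, Pearson 0.452). Genes are not independent replicates, and the pair was picked after its values were seen. In control library 3 moulting genes (0.45) and adult cuticle genes (0.74) were above the control mean on the log2 scale. In libraries 1, 2 and 3 labelled fars-1 RNAi moulting genes were above it, but adult cuticle genes were at -0.64, -1.60 and -3.10. The correlation therefore does not show that the shared axis is stage. An effect of fars-1 RNAi itself was not tested apart from stage, and stays open too.

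The acdh-1 transcript was almost lost. Reads assigned instead to the related gene acdh-2, on another chromosome, are argued against, since acdh-2 also fell, from 5.91 ± 3.19 to 0.00998 ± 0.0173 CPM, a change of -1.80% of what acdh-1 lost. Its log2 fold change was -8.59, and -10.47 without fars-1 RNAi replicate 2. A different supply of vitamin B12 from the bacteria could lower the propionate shunt together, but the test did not decide: hphd-1 was at -2.41 and hach-1 at -1.43, while alh-8 was at -0.22, or 0.33 with upper-quartile scaling, and lost its call with total counts (-0.10), CPM of at least 1 (-0.16), the replicate block (-0.22) or limma on log2(TPM + 1) (-0.02), and without fars-1 RNAi replicate 2 (-0.22) or 3 (-0.19). An effect of fars-1 RNAi was not tested apart from these and stays open.

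For the number of genes called, the 6 libraries can be split into 3 and 3 in 10 ways. The real split called 13368 genes and the highest of the others 0, so 1 of the 10 splits, the real one itself, reached that number. A split that mixes the groups puts their difference into the spread within each side, so few calls were to be expected there. With 10 splits the share cannot be under 0.05.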
